A study of Mus musculus with 2 samples.

How the data were processed

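Total RNA-seq libraries from gastrocnemius muscle of 2 female B6Cast F1 mice were used. Per the labels they are biological replicates 1 and 2 of 1 group, from tissue samples with different identifiers, made from 300 ng of total RNA with ERCC spike-ins for ribosome-reduced stranded libraries. The donor identifier is shared and names the strain, so separate animals are taken from the sample labels alone. Per the notes deposited with each library, the build was mm10 and the annotation GENCODE M21. The aligner and the versions of the quantifiers are not given in the sources used here.

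The deposited expected counts of genes and transcripts carry the column names that RSEM writes, per the file headers, and were made by the authors from transcriptome alignments. Estimated counts per transcript in another deposited table carry the column names of kallisto, per the file headers, and were made from the FASTQ reads. Deposited TPM values were taken as given, and those of RSEM run over all rows, spike-ins included. FPKM values were deposited by the authors beside them and were not used here. The deposited percent of each gene's TPM per transcript was not used, and transcript percents were computed from TPM. RSEM also gives posterior mean TPM, which served as an alternative, and other deposited columns hold bounds of the tool's intervals, which were not used here. Kallisto values were summed per gene.

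The gene table held 55536 genes, all matched to GENCODE M21, and 96 spike-in rows, 1 phiX row and 26248 tRNA rows. The phiX row had 0 counts and the tRNA rows had 1 count in replicate 1 and 2 in replicate 2, and both stayed out of every test. Expected counts of genes summed to 38654555 and 43722892, and 70 and 73 spike-ins had counts above 0. A list symbol held by several genes took the gene of highest mean TPM, a choice made after the data were seen.

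Expected counts were rounded to whole numbers. TMM factors and log2 CPM (prior count 2) came from edgeR 4.0.16 in R 4.3.3, over genes with a summed count of at least 50, and the log2 ratio is always replicate 2 over replicate 1. The biological coefficient of variation is the square root of edgeR's common dispersion over 14223 genes kept by filterByExpr with a minimum count of 10. DESeq2 1.42.0 gave size factors as an alternative. Fold intervals at 95% are exact conditional binomial intervals, scaled by effective library size. They cover counting error only, since reads without molecular identifiers are not independent molecules. With 2 values a paired exact test cannot go below p = 0.5, so no test of a difference was made. A gene list's median was placed among 10000 random lists of the same size, matched on deciles of mean expression, where at least 4 members were tested. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 did the rest.

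The gene lists, the settings and the rule for named genes were fixed before the data were examined, except for 5 alternatives and the lists of glucocorticoid and fasting targets, which were added later. The rule took the 10 genes of highest mean TPM outside mitochondrial, spike-in and ribosomal rows, up to 3 top members of each list, all adult myosin heavy chains, members with no counts, the 8 largest rises and 8 largest falls among protein-coding genes with a mean of at least 5 TPM, the 3 farthest members of each list standing apart, and isoform genes. The isoform genes were the 6 of highest TPM whose top transcript takes under 90%, with Tnnt3, Tpm1, Pkm, Myl1, Ldb3 and Bin1 in any case. Some genes that the rule names are not reported here. Alternatives were other scalings, count filters, prior counts, expression estimates and TPM minimums, and leaving out each library.

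The steps were tested on simulated data, in 10 pairs of libraries at the real means and library sizes over about 12939 tested genes, with a coefficient of variation of 0.2 and 200 genes changed per pair. At 2-fold, 3-fold, 4-fold and 8-fold, 51.8%, 90.8%, 98.8% and 100% of the changed genes passed the 2-fold rule in the right direction, and 2.46% of unchanged genes passed it. A shift of 1 in the slow fibre list was recovered as 0.968 and stood apart in all 10 pairs. Of 290 lists without slow fibre genes, 11 stood apart (3.79%), though some may hold changed genes. Genes were simulated independently of each other, so this rate does not cover lists of co-regulated genes. The recovered coefficient of variation was 0.198 with no changed gene and 0.229 with the changed genes in place.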

Results

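Total RNA was sequenced from the gastrocnemius, the large mixed-fibre muscle of the calf, of female F1 mice from a cross of C57BL/6J and CAST/EiJ parents, aged 18 to 20 months per the labels. The labels describe 1 group of 2 replicates from separate tissue samples, with 300 ng of input RNA each and ERCC spike-ins, a set of synthetic RNAs added in known amounts. The expected counts summed to 38819119 in replicate 1 and 43918877 in replicate 2. With 1 group there was no comparison between conditions, and no younger group was analysed here. The design implies a description of the aged muscle and of the spread between its replicates. Values are means ± SD of the 2 libraries (n = 2) unless both are given, and intervals cover counting error only.

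The transcriptome was that of a fast muscle. The most abundant nuclear messenger RNAs were Acta1, the skeletal muscle actin, at 22438 ± 867 TPM, and Ckm, the muscle creatine kinase, at 19315 ± 769 TPM. Tnnt3, the fast troponin T, stood at 16896 ± 2049 TPM, and Myh4, the myosin heavy chain of the fastest (IIB) fibres, at 12978 ± 2167 TPM. All 14 genes of the fast fibre list were at or above 1 TPM in both libraries, with a median of 7058 ± 11.6 TPM. Mylpf, the fast regulatory light chain, reached 12674 ± 126 TPM. All 14 genes of the slow fibre list were detected too, at a median of 142 ± 131 TPM. The summed TPM of the slow list was 0.0102 of that of the fast list in replicate 1 and 0.0414 in replicate 2, so the SD was of the order of the mean (0.0258 ± 0.0221).

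Among the adult myosin heavy chains, Myh4 (ENSMUSG00000057003.12, chromosome 11, 67238029 to 67260446, mm10) took 85.3 ± 9.92% of the summed TPM. Myh1, the heavy chain of IIX fibres, took 8.16 ± 4.996%, and Myh2, that of IIA fibres, took 4.96 ± 3.24%. Both had fractional expected counts. By kallisto, Myh1 was at 1508 and 3349 TPM, against 727 and 1709 TPM by RSEM, so its level and share depend on the tool. Myh7 (chromosome 14, 54970684 to 54994626), the heavy chain of slow fibres, took 1.61 ± 1.68%. The Myh4 share was 92.3% in replicate 1 and 78.3% in replicate 2. Of the 9 other myosin heavy chains, 6 were at or above 1 TPM in both libraries. Myh8, the perinatal isoform, led with 130 ± 18.8 TPM, followed by Myh6 at 49.1 ± 47.6 TPM and Myh14 at 20.3 ± 1.90 TPM. Myh6 and Myh7 are near-identical neighbours, and both had fractional expected counts, so the level of the less abundant Myh6 is uncertain. Myh4 and Myh8, both on chromosome 11, had fractional expected counts too, so the level of the far less abundant Myh8 is also uncertain. Of the common sarcomere genes, Tpm1 (11549 ± 1367 TPM) and Neb (2674 ± 354 TPM) followed Acta1.

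Among the nuclear gene lists of energy metabolism, glycolysis had the highest median. All 18 glycolysis and glycogen genes were detected, with a median of 746 TPM in both libraries. Aldoa, an aldolase, was at 12448 ± 926 TPM, Gapdh at 4971 ± 53.2 TPM, and Pygm, the muscle glycogen phosphorylase, at 3842 ± 264 TPM. By kallisto, Aldoa was at 17260 and 14532 TPM and Gapdh at 15347 and 13855 TPM, so the level of Gapdh depends on the tool. The 31 nuclear genes of oxidative phosphorylation had a median of 256 ± 50.9 TPM, and their highest members were Atp5b (1327 ± 219 TPM), Cox8b (807 ± 120 TPM) and Atp5a1 (711 ± 119 TPM). The 19 genes of fatty acid use had a median of 96.7 ± 24.7 TPM. Pdk4, a kinase that restrains glucose oxidation, led them at 373 ± 285 TPM, ahead of the fatty acid carrier Fabp3 (192 ± 109 TPM) and Hadhb (154 ± 31.0 TPM). The 13 mitochondrial messenger RNAs took 7.41 ± 1.08% of all TPM, led by mt-Co1 (15398 ± 3306 TPM), mt-Cytb (10185 ± 1393 TPM) and mt-Nd1 (8774 ± 1092 TPM). The nuclear mitochondrial-like pseudogenes Gm10925, Gm28661 and Gm28437 on chromosome 1 were listed at 18643 ± 2402, 18277 ± 2834 and 14363 ± 2604 TPM. They share sequence with mitochondrial genes, so the split of reads between these copies is uncertain. The order of the mitochondrial messenger RNAs given above is therefore uncertain too. With the chromosome 1 copies added, the share was 13.2%.

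By RSEM, noncoding RNA made up a large part of the TPM. Rn7s1 and Rn7s2, copies of the RNA of the signal recognition particle, were listed at the same 119386 ± 12646 TPM each, with identical counts, so the split between them is uncertain. Together they took 23.9 ± 2.53% of TPM but 3.58 ± 0.378% of expected counts, since they are short. Rn7sk, a regulator of transcription elongation, was at 15807 ± 3381 TPM by RSEM and listed at 0 by kallisto. The mitochondrial ribosomal RNAs mt-Rnr2 and mt-Rnr1 were at 57724 ± 13724 and 45678 ± 8352 TPM. Genes that the annotation calls long noncoding took 1.20 ± 0.181% of TPM, and Gm26917 and Gm42418 alone took 0.689 ± 0.116%. Without these 2 genes the share was 0.512%, and the origin of their reads was not tested. Malat1, a nuclear long noncoding RNA, was at 1049 ± 337 TPM. Nuclear protein-coding genes took 46.2 ± 0.704% of TPM, 67.9 ± 3.82% of kallisto TPM and 76.2 ± 2.42% of expected counts. In all, 10943 genes were at or above 1 TPM in both libraries, of which 10015 were protein coding and 354 long noncoding.

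Genes of excitation and contraction were abundant, and 17 of 18 were at or above 1 TPM in both libraries. Ryr1, the calcium release channel, was at 798 ± 73.1 TPM, Trdn at 672 ± 62.1 TPM and Cacna1s at 443 ± 10.9 TPM. The synapse and denervation genes were low, at a median of 5.93 ± 0.113 TPM, led by Hdac4 (40.8 ± 12.8 TPM), Gadd45a (29.2 ± 14.6 TPM) and Chrnb1 (21.6 ± 11.5 TPM). All 21 atrophy and autophagy genes were detected, led by the autophagy receptor Sqstm1 (266 ± 53.7 TPM) and the ubiquitin ligases Trim63 (201 ± 0.877 TPM) and Fbxo32 (140 ± 60.0 TPM). Of the 16 senescence and secretory genes, 8 were at or above 1 TPM in both libraries, led by Igfbp5 (72.2 ± 15.2 TPM), the cell cycle inhibitor Cdkn1a (39.1 ± 16.1 TPM) and Cxcl12 (19.3 ± 2.72 TPM). Interferon-response genes were low, with 4 of 16 at or above 1 TPM in both libraries. They included Ifi27l2a (5.72 ± 1.51 TPM) and Bst2 (3.04 ± 0.622 TPM). Of the circadian genes, Tef (69.9 ± 0.332 TPM), Rora (44.9 ± 10.9 TPM) and Nr1d1 (43.1 ± 15.1 TPM) were highest. Of the imprinted genes, H19 led with 256 ± 112 TPM, ahead of Snrpn (30.035 ± 0.134 TPM) and Igf2r (20.1 ± 1.58 TPM). Nr4a1 (78.7 ± 16.6 TPM), Jun (35.3 ± 14.8 TPM) and Hsph1 (26.6 ± 0.445 TPM) led the immediate early and stress genes.

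Among sex-linked genes, Xist, the RNA that silences the inactive X chromosome, was at 16.3 ± 5.99 TPM, and Ddx3x, Eif2s3x and Kdm6a were at 101 ± 19.6, 49.1 ± 6.26 and 17.3 ± 4.43 TPM. By RSEM, Ddx3y, Uty, Kdm5d, Usp9y, Zfy1 and Sry had no counts in either library, and Eif2s3y was listed at 0.02 TPM in replicate 2 and 0 in replicate 1. By kallisto, Uty was listed at 0.565 and 0.479 TPM, Kdm5d at 0.177 and 0.0952 TPM, Ddx3y at 0.167 and 0 TPM, Sry at 0.0466 and 0 TPM and Usp9y at 0.0151 and 0.0335 TPM, and Zfy1 at 0 in both. An RSEM count of 0 allowed up to 3 counts, or 0.0773 CPM in replicate 1 and 0.0683 in replicate 2.

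Of the 13 marker lists of other cell types, 8 had a median at or above 1 TPM in both libraries. Fibro-adipogenic markers had a median of 17.3 ± 8.73 TPM, with Gsn at 234 ± 5.72, Dcn at 119 ± 19.8 and Smoc2 at 30.3 ± 1.67 TPM. Erythrocyte markers had a median of 14.04 ± 2.52 TPM, with the globins Hbb-bs, Hba-a1 and Hba-a2 at 146 ± 9.91, 137 ± 1.68 and 113 ± 5.61 TPM. Which of these lists ranked first varied: the erythrocyte median was higher in replicate 1 (15.8 against 11.1 TPM) and by kallisto (41.2 against 21.1 TPM), and the fibro-adipogenic median in replicate 2 (23.4 against 12.3 TPM). The near-identical Hba-a1 and Hba-a2 share reads. Endothelial markers had a median of 7.96 ± 0.0778 TPM, led by Cdh5 (14.5 ± 0.283 TPM), Pecam1 (13.4 ± 2.02 TPM) and Egfl7 (12.4 ± 5.34 TPM). Mural and smooth muscle markers had a median of 4.94 ± 0.304 TPM, led by Rgs5 (59.5 ± 10.4 TPM), Abcc9 (59.0 ± 1.39 TPM) and Acta2 (25.1 ± 3.49 TPM). Adipocyte markers (4.03 ± 0.842 TPM) were led by Plin4 (90.1 ± 18.3 TPM), which muscle fibres also express, then Fabp4 (57.8 ± 2.90 TPM) and Cfd (45.7 ± 4.18 TPM). Tendon markers (3.31 ± 1.05 TPM) were led by Thbs4 (27.5 ± 7.59 TPM), Fmod (24.3 ± 8.94 TPM) and Scx (8.01 ± 2.36 TPM). Macrophage markers (2.61 ± 0.488 TPM) were led by Lyz2 (15.0 ± 3.39 TPM), C1qa (4.03 ± 0.276 TPM) and C1qb (3.61 ± 0.170 TPM), and satellite and myogenic markers (2.11 ± 0.325 TPM) by Des (1073 ± 14.3 TPM), Myf6 (63.7 ± 30.4 TPM) and Sdc4 (23.9 ± 4.91 TPM). Muscle fibres also express Des and Myf6.

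Schwann cell, mast cell and lymphoid lists had lower medians. The Schwann cell list had a median of 1.02 ± 0.325 TPM, with Mbp at 14.1 ± 4.86 and Pmp22 at 12.4 ± 0.955 TPM. Mast cell markers had a median of 0.868 ± 0.279 TPM, led by Tpsb2 (1.62 ± 0.651 TPM), Cma1 (1.24 ± 0.290 TPM) and Cpa3 (0.955 ± 0.375 TPM). The B and plasma cell list had a median of 0.185 ± 0.0212 TPM, although its top members Ighm and Igkc, immunoglobulin constant genes, stood at 41.3 ± 29.7 and 3.77 ± 4.83 TPM, ahead of Jchain (0.48 ± 0.311 TPM). Of the T and natural killer cell markers, Cd3e, Cd3g, Cd8a, Cd8b1, Nkg7 and Klrb1c had no counts in either library by RSEM, and the highest by RSEM were Trac (0.220 ± 0.170 TPM), Cd4 (0.165 ± 0.0212 TPM) and Gzma (0.020 ± 0.028 TPM). By kallisto, Cd8a was listed at 0.179 and 0.296 TPM, and Cd3e and Cd3g at 0.0289 and 0.0295 TPM in replicate 2 alone. Of the neutrophil markers, Ly6g, Ngp, Camp and Cxcr2 had no counts by RSEM, while kallisto listed Cxcr2 at 0.530 and 0.329 TPM. By RSEM, S100a9 was at 0.120 ± 0.0707 TPM, S100a8 at 0.045 ± 0.064 TPM and Retnlg at 0.035 ± 0.050 TPM. By RSEM each of these T cell, natural killer cell and neutrophil markers had at most 5 counts in a library. Marker levels were not converted to shares of cells.

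**Figure D1:**
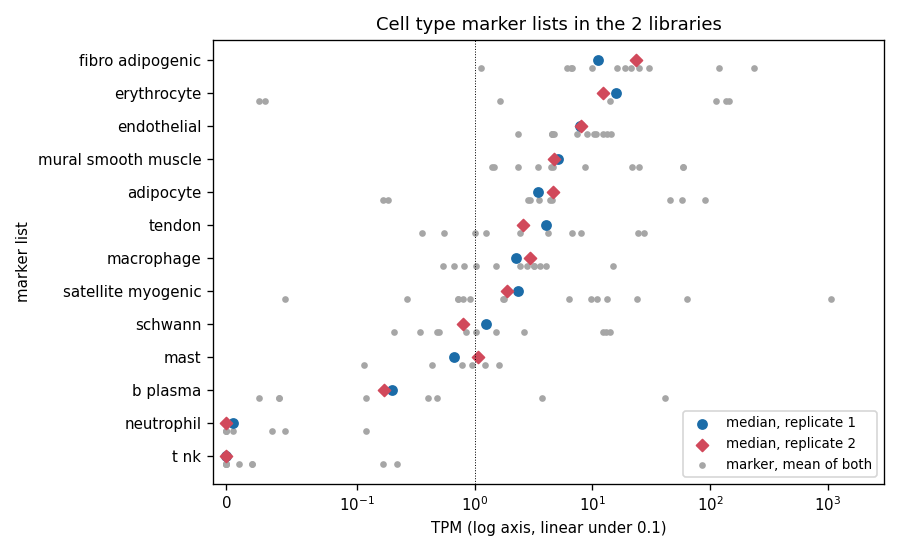
Median TPM of 13 cell type marker lists in replicate 1 (circles) and replicate 2 (diamonds), with each marker's mean TPM in grey, on an axis that is logarithmic above 0.1 TPM. The erythrocyte median was highest in replicate 1 (15.8 TPM) and the fibro-adipogenic median in replicate 2 (23.4 TPM), and the neutrophil and T cell lists sat at or near 0.

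The libraries ranked genes alike. Across genes, log2(TPM + 1) correlated with a Pearson r of 0.992, and TPM with a Spearman rho of 0.921. These are correlations across genes, which are not independent replicates. Of 12969 genes with a summed expected count of at least 50, 86.3% lay within 1.5-fold of each other after TMM scaling. The biological coefficient of variation was 0.194. The chi-square of the counts per degree of freedom was 94.8 over genes and 1.33 over 38 spike-ins. The log2 TPM ratio had an SD of 0.16 over these 38 spike-ins and of 0.03 over the 15 with at least 1000 counts. Spike-ins took 0.758 ± 0.0244% of TPM.

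Slow fibre genes stood higher in replicate 2 than in replicate 1, together with genes of oxidative metabolism, while the fast list was level. All 14 slow fibre genes were at least 2-fold higher, with a median log2 ratio of 2.23, above the central 95% of 10000 random lists of matched expression. Tnnt1 (ENSMUSG00000064179.13, chromosome 7, 4504570 to 4516382), the slow troponin T, was 7.29-fold higher (95% counting interval 6.88 to 7.73), at 50.2 against 329 TPM. Tnnc1 and Tnni1, the slow troponins C and I, were 6.74-fold (6.29 to 7.23) and 6.38-fold (5.92 to 6.89) higher. Fhl1, Mybpc1 and Myl2, the most abundant members, had log2 ratios of 2.10, 1.24 and 2.53. The fast list had a median of 0.05, and none of its 14 genes differed 2-fold. Each comparison here sets 1 library against 1, so it has no replicate check and no p-value, and it describes these libraries.

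**Figure D2:**
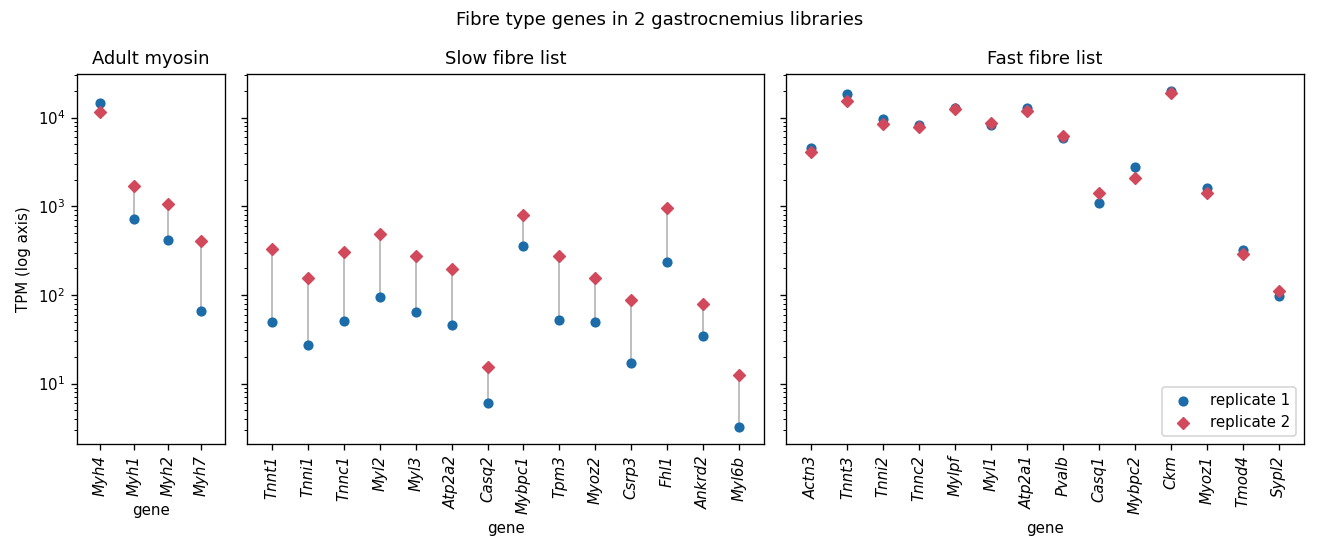
TPM on a log axis of the adult myosin heavy chains, the slow fibre list and the fast fibre list in replicate 1 (circles) and replicate 2 (diamonds), joined by a line per gene. All 14 slow fibre genes were higher in replicate 2, while no fast fibre gene differed 2-fold.

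The adult myosin heavy chains moved with the slow list. Myh7 was 6.48-fold higher in replicate 2 (6.33 to 6.63), Myh2 2.81-fold (2.79 to 2.84) and Myh1 2.60-fold (2.58 to 2.62), while Myh4 had a log2 ratio of -0.19. The median over the 4 genes was 1.43, and 1 of them, Myh4, was below 0. Among the other myosin heavy chains, Myh6, Myh7b and Myh13 had log2 ratios of 2.64, 2.22 and 1.14, and the list's median was 0.33. The common sarcomere list had a median of 0.23. Its members farthest up were Myom3 (1.82), Tpm2 (1.69), the tropomyosin shared by slow and fast fibres, and Actn2 (1.33), whereas Acta1 stood at 0.23.

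All 31 nuclear genes of oxidative phosphorylation were above 0, with a median log2 ratio of 0.52 and 1 gene past 2-fold, Cox7a1 (1.05). Sdhb and Cyc1 followed at 0.79 and 0.74. Of the 13 mitochondrial messenger RNAs, 12 were above 0, with a median of 0.41, led by mt-Co2 (0.90), mt-Nd6 (0.62) and mt-Co1 (0.59). The mt-Co2 value rests on 68.2 and 115 TPM by RSEM, against 1101 and 1162 TPM by kallisto, and is uncertain. Of 19 fatty acid genes, 18 were above 0 and 6 at least 2-fold higher, with a median of 0.62. Ppara, a nuclear receptor that drives fatty acid oxidation, was 4.47-fold higher (3.80 to 5.29), Pdk4 3.55-fold (3.48 to 3.62) and Ucp3 2.69-fold (2.56 to 2.82). Glycolysis genes had a median of 0.15, and none differed 2-fold.

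In all, 602 of the 12969 genes differed at least 2-fold, 350 of them higher in replicate 2 and 252 lower. Under spike-in totals in place of TMM, the median of all genes shifted from 0 to -0.22, and 244 genes were higher and 440 lower. Ratios here are relative to the TMM scaling, and those between 0 and 0.22 turn below 0 under spike-in totals, Fabp4 (0.21) among them. Of the 8 protein-coding genes farthest above 0 with a mean of at least 5 TPM, 4 were Myh7, Tnnt1, Tnnc1 and Tnni1. Others were Ddit4 (ENSMUSG00000020108.4, chromosome 10, 59949669 to 59951834), a stress-induced inhibitor of mTORC1, at 15.3-fold (13.7 to 17.3), Zfp385a (7.29-fold, 6.10 to 8.76) and Gadd45g (6.28-fold, 5.49 to 7.21). Farthest below 0 in the same set was Ankrd1 (ENSMUSG00000024803.9, chromosome 19, 36111961 to 36120099), a stretch-responsive muscle ankyrin repeat protein, which was 16.9-fold lower (12.6 to 23.1), at 14.7 against 0.780 TPM. Stk33 was 7.17-fold lower (5.56 to 9.39), Tmem100 6.07-fold (5.35 to 6.91), Eda2r 4.89-fold (4.44 to 5.39) and Pamr1 4.18-fold (3.62 to 4.86). Socs2 and Cish, which are induced by cytokine receptors and the growth hormone receptor, were 3.71-fold (3.30 to 4.18) and 3.38-fold (2.70 to 4.26) lower, and Enox2 was 3.18-fold lower (2.90 to 3.49).

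Markers of other cell types also differed between the libraries. Of the fibro-adipogenic genes, 11 of 12 were above 0, with a median log2 ratio of 0.42, and the collagens Col3a1, Col1a1 and Col1a2 stood at 1.87, 1.70 and 1.36. All 8 tested adipocyte genes were above 0 (median 0.50), led by Pck1 (2.19), Retn (0.97) and Cidec (0.76). The Retn value rests on 46 and 94 counts by RSEM, against 2.56 and 2.73 TPM by kallisto, and is uncertain. All 4 tested mast cell genes were above 0 (median 0.89), led by Tpsb2 (0.99), Cpa3 (0.92) and Kit (0.86). For Kit the TPM went the other way, from 0.480 to 0.390. Of the satellite and myogenic genes, 9 of 14 were below 0 (median -0.51), with Myod1 at -1.46, Myf5 at -0.96 and Myf6, which fibres also express, at -0.86, while Sdc4 (0.55) and Des (0.13) were above 0. Of the tendon genes, 7 of 8 were below 0 (median -0.47), with Comp, Col22a1 and Fmod at -0.69, -0.64 and -0.62. Of the endothelial genes, 7 of 12 were below 0 (median -0.17), with Cldn5, Egfl7 and Vwf at -0.97, -0.78 and -0.76. This sign turned to 0.03 when only genes with at least 500 counts were kept. All 5 tested genes of MHC class II, the antigen-presenting complex, were below 0, with a median of -0.76 and with H2-Aa, H2-Eb1 and H2-Ab1 at -1.12, -1.04 and -0.76. Abundant noncoding RNAs (median -0.26) had 10 of 12 tested members below 0, among them Xist (-0.69), Malat1 (-0.56) and Rmrp (-0.44), while the most abundant, mt-Rnr2 (0.64) and mt-Rnr1 (0.52), were above 0. The female X-linked list had a median of -0.23, with Xist, Kdm6a (-0.43) and Ddx3x (-0.23) lowest.

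Of 30 lists compared, 16 stood outside the central 95% of matched random lists, 10 higher and 6 lower, where chance would place 5% of lists of independent genes. Members of a list are co-regulated and some lists share genes, so more than 5% can stand apart without a cause specific to each list. The calls of the other myosin, common sarcomere and endothelial lists were lost when only genes with at least 500 counts were kept, and that of the other myosins also with TPM + 1 (0.0086). At 500 counts 10 of the 16 calls were kept, and 3 lists that stood apart (MHC class II, mast cell and adipocyte) had too few genes to be compared. That of MHC class II was lost by kallisto and that of the mast cell list with a mean. That of the female X-linked list was lost among protein-coding genes and with each gene kept in 1 list (-0.19). The lists inside that range were those of glycolysis, fast fibre, excitation and contraction (0.08), synapse and denervation (0.10), atrophy and autophagy (-0.02), senescence (0.18), interferon (0.04), circadian (-0.04), imprinted (0.14), immediate early (0.09), mural (-0.08), macrophage (0.22), Schwann cell (-0.19) and erythrocyte genes (0.01). Of these, the imprinted list stood apart in 5 alternatives, with up to 0.32 for a mean, and the immediate early list at 500 counts (1.45) and with a mean (0.49). The atrophy and autophagy list stood apart with a mean (0.40), and the synapse and denervation list at 500 counts (-0.23), by kallisto (0.17) and with TPM + 1 (0.03). A median near 0 did not mean that members were level, since 6 of the 21 atrophy and autophagy genes and 5 of 14 immediate early genes were at least 2-fold higher.

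**Figure D3:**
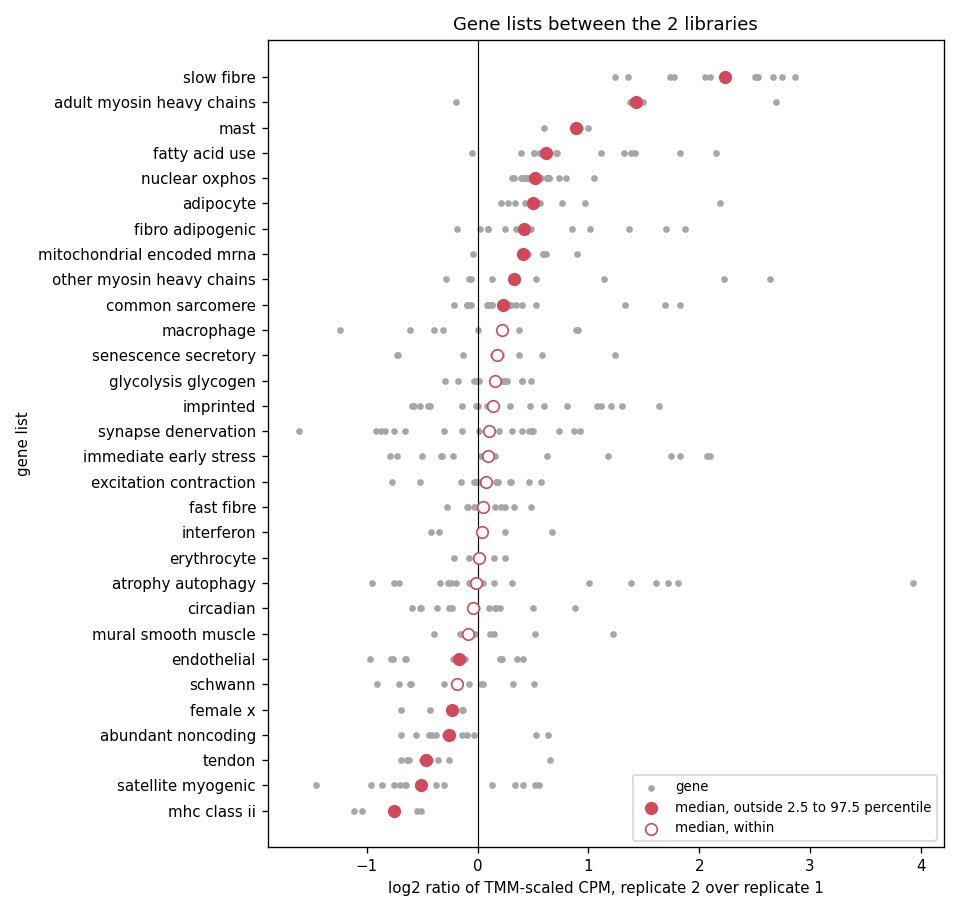
Log2 ratio of replicate 2 over replicate 1 for the tested genes of 30 lists (grey) and their medians (circles, filled where the median lay outside the central 95% of 10000 matched random lists). The slow fibre list had the highest median (2.23) and the MHC class II list the lowest (-0.76).

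The transcript tables gave estimates of isoform use in muscle genes, which differed between the tools. In 20 of 26 muscle genes listed beforehand for isoforms, RSEM and kallisto put the same transcript first. For Tpm1, Tpm1-205 took 97.6 ± 0.318% of the gene's TPM by RSEM and 75.9 ± 0.615% by kallisto. Ldb3-207 took 80.2 ± 0.320% and 77.0 ± 0.523%, and Bin1-205 took 81.4 ± 0.513% and 58.1 ± 1.57%. For Ckm, Ckm-201 took 58.8 ± 0.0734% and 50.7 ± 0.503%. For Pkm, RSEM put Pkm-202 first (54.3 ± 0.817%) and kallisto put Pkm-201 first (44.9 ± 1.44%). Neb-202 took 21.2 ± 0.440% and 26.2 ± 1.03%, and Tpm2-202 took 43.5 ± 1.34% and 51.8 ± 2.15%. For Tnnt3, the top transcript by RSEM differed between the libraries, with Tnnt3-224 at 51.4 and 33.6% and Tnnt3-201 at 37.99 and 49.51%. By kallisto, Tnnt3-224 took 20.97 ± 3.85% and Tnnt3-201 0%, with Tnnt3-225 first at 41.4%. The tables also parted on Myl1, where RSEM gave Myl1-202 75.6 ± 2.29% and kallisto 18.0 ± 7.71%, with Myl1-207 first at 42.1%.

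Over 5961 genes with at least 5 TPM in both libraries and at least 2 annotated transcripts, the top transcript was the same by RSEM and kallisto in 74.4 ± 0.142%. Within a tool, it was the same in both libraries in 92.4% of genes by RSEM and 89.7% by kallisto, so the tools differed by more than the libraries. Short RNAs had fewer reads in the kallisto tables. Genes whose main transcript had up to 200 bases had 23.1% as many reads by kallisto as by RSEM, those of over 200 and up to 300 bases 8.02%, those of over 300 and up to 400 bases 38.8%, and those over 4000 bases 107%. Rn7s1 and Rn7s2 took 23.9% of TPM by RSEM and 1.93e-04% by kallisto.

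**Figure D4:**
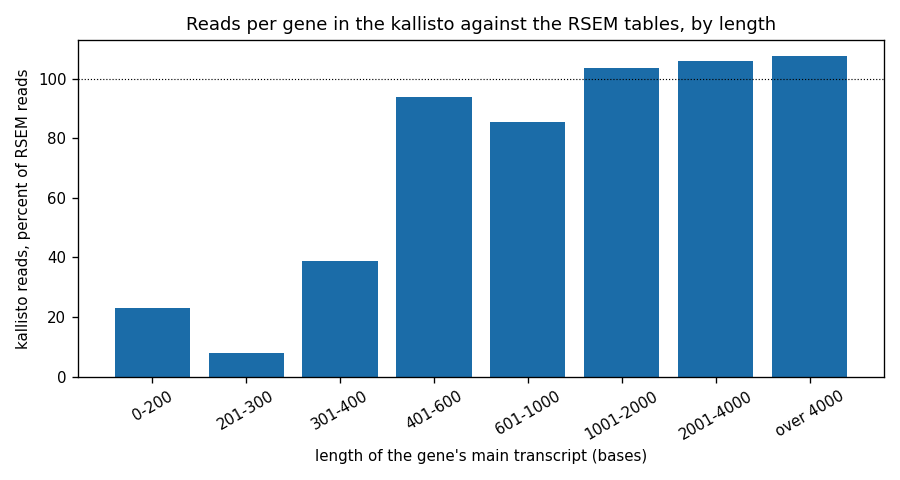
Reads assigned by kallisto as a percent of those assigned by RSEM, summed over both libraries for genes with a mean of at least 1 TPM, by the length of the gene's most abundant transcript. Bars start at 0 and the dotted line marks 100%. The bar for 201 to 300 bases stands at 8.02% and that for over 4000 bases at 107%. Most RSEM reads behind the bar for 201 to 300 bases are of Rn7s1 and Rn7s2.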

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

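Alternatives named here as added, namely the chromosome 1 copies, the exclusion of Gm26917 and Gm42418, the 3-fold minimum, the exclusion of transcripts under 300 bases and the single-list assignment, were chosen after seeing the data. No paired analysis was possible because there is 1 group. Differences between libraries cannot be computed without either library. Leaving out a library moves a mean of 2 by less than 1 SD by construction, so its range is only the 2 values: 78.3 to 92.3% for the Myh4 share, 0.0102 to 0.0414 for the slow to fast ratio, 6.64 to 8.17% for mitochondrial mRNA, 1.07 to 1.33% for long noncoding RNA, 0.741 to 0.776% for spike-ins, 11287 to 11546 genes detected, 9 marker lists in either case, and 74.3 to 74.5% transcript agreement.

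The Myh4 share and the slow to fast ratio stayed within 1 SD under every other estimate. This is a weak check, since the libraries differ and the SDs are wide (9.92% and 0.0221). Over these estimates the share ran from 81.2% (kallisto) to 85.8% (expected counts). The ratio ran from 0.0202 (medians of the lists) to 0.0361 (expected counts). The mitochondrial mRNA share was 9.81% by kallisto, 5.04% of expected counts, 17.8% with the mitochondrial rRNAs and 13.2% with the chromosome 1 copies. The long noncoding share was 1.61% by kallisto, 2.04% of counts and 0.512% without Gm26917 and Gm42418. The spike-in share was 0.874% by kallisto and 0.435% of counts. At 5 TPM, 6725 genes were detected, since fewer pass a higher minimum. The correlation was 0.987 with a pseudocount of 0.1, 0.992 (0.9915) with 5, 0.977 over genes at or above 1 TPM and 0.991 by kallisto. The coefficient of variation was 0.218 under spike-in totals, 0.211 without a filter, 0.179 at 500 counts and 0.187 over nuclear protein-coding genes. The 602 genes differing 2-fold became 2712 without a filter, 194 at 500 counts, 252 with TPM + 1 and 203 at 3-fold. The balance of 350 higher and 252 lower turned without a filter (1090 and 1622) and widened at 500 counts (147 and 47). The filters and the threshold set how many genes can pass. TPM + 1 changes unit, scaling and pseudocount together, and its cause was not tested. Transcript agreement was 74.5% at 1 TPM and 70.1% at 50 TPM, and the cause was not tested. Of 264 list medians under alternatives, 245 kept their call or lack of one, 7 lost a call with the same sign, 11 gained one and 1 lost its call and turned: the endothelial list stood at 0.033 at 500 counts, and the cause was not tested. The sign changed in 26 medians in all. Ratios were followed for the adult myosins and for genes named for the largest or farthest ratios. Of 519 such ratios, 503 kept their side of 2-fold, 9 lost it, 7 gained it and 0 turned. Most of these genes were picked by their ratios in these data, so the count does not speak for named genes in general. Of 39 cell type medians, 27 moved by over 1 SD. The marker lists at or above 1 TPM were 8, and 9 by posterior mean TPM, 9 by kallisto and 10 with TPM rescaled over nuclear protein-coding genes, which raised the fibro-adipogenic median to 37.6 and the endothelial median to 17.2 TPM. The slow fibre list stood apart in each setting tried, with medians down to 2.01 under spike-in totals.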

Other observations

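The tests of shared reads, of dissection, of fibre type and of the 3 explanations for noncoding RNA were chosen after the result was seen; those of length and GC, glucocorticoid targets and fasting targets were written after the patterns were seen but before the values they measure. The dilution test was replaced more than once after values were known, since earlier versions could not decide it. The last version sets an unscaled share beside a scaled ratio, so it does not decide it either.

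Of 4 tested immunoglobulin constant genes, 3 were lower in replicate 2 and Ighm was higher. Ighm, the heavy chain of IgM, was 3.41-fold higher in replicate 2 (3.17 to 3.67), at 20.3 against 62.3 TPM. Igkc, the kappa light chain, was 18.4-fold lower (7.59 to 58.0), on 90 and 5 counts, and Jchain was listed at 0.7 and 0.26 TPM. Small RNA classes were lower in replicate 2: all 23 tested small nuclear RNAs and 31 of 34 small nucleolar RNAs had log2 ratios below 0.

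Slow fibre genes were higher in replicate 2 by a median log2 ratio of 2.23. Removal of a cubic trend on length and GC left 2.19, and the 12 members with whole expected counts, to the decimals deposited, had a median of 2.16, so neither accounts for the whole pattern. What stays open is whether a different part of the muscle or some of an adjoining slow muscle was dissected or the animals differ in fibre makeup, which 1 library per animal cannot separate. No biological explanation was tested against a group, since there is 1 group. Tests of scaling and of denervation were taken out of the set once their values were known. The lowest slow list median over the scalings was 2.01, against scaling. The values for denervation decided nothing, and it stays open. The synapse and denervation genes went both ways (10 above and 8 below 0), with a median of 0.10 that was -0.23 at 500 counts.

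Ddit4, Zfp36, Mt2, Mt1 and Cebpd, chosen after their values were seen, had log2 ratios of 3.93, 2.10, 1.81, 1.72 and 1.61. The immediate early and stress list, which holds Zfp36, had a median of 0.09, with 6 of 14 genes below 0. This list was not level, since 5 genes were at least 2-fold higher and 0 were 2-fold lower. Its value was 1.45 at 500 counts and 0.49 with a mean. Further glucocorticoid targets had a median of 0.381 (99.9 percentile of matched lists, 9 of 12 above 0), but Fkbp5 and Sgk1, standard targets, stood at -0.82 and -0.36. Further fasting targets had a median of 0.568 (8 of 10 above 0), led by Angptl4 at 2.23. Both states may contribute, as hypotheses, though fasting targets could also follow fibre type. A difference in fibre type alone stays open, since nothing bounds it: the median of the 5 picked genes is 1.81, and Ddit4 lies above every slow list member (highest 2.86).

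Small nuclear, nucleolar and Cajal body RNAs were lower in replicate 2, with a median log2 ratio of -0.64 over 63 genes. Dilution by mitochondrial RNA would lower all other genes alike, and TMM scaling takes such a shift out. It can therefore not account for this scaled ratio, whatever its size. Before scaling, the share of counts outside mitochondrial genes and their chromosome 1 copies differed by a log2 ratio of -0.0797. That value is not on the scale of the -0.64 and does not test it. A loss of short RNA could not be decided, since 5 long nuclear noncoding RNAs, Malat1 among them, had a median of -0.38, between the bounds set. They ran from -0.69 (Xist) to -0.14 (Kcnq1ot1). Other short RNAs did not decide it either, with Rn7s1 and Rn7s2 at -0.0675, Rn7sk at -0.29 and Rmrp at -0.44. A lower nuclear RNA fraction may fit the level Rn7s1 and Rn7s2 (-0.0675), which are cytoplasmic, and it stays open, since these values had been seen.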
